A study of Mus musculus with 6 samples.

How the data were processed

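Lung tissue of 6 male C57BL/6J mouse samples, 3 kept at room temperature and 3 held at 4 °C for 6 h, was profiled by RNA sequencing. Total RNA libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. Whether the libraries keep strand is not stated, so reads of a gene and of an antisense or overlapping neighbour cannot be told apart. Reads were placed on genome build mm10, per the submitters' processing notes. The aligner, the counter and the annotation are not given in the sources used here.

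The deposited table gives 1 RPKM value per gene and library, made by the authors and rounded by them to 3 decimals. It is named as raw counts, but its values are not whole numbers. Each value was tested against gene lengths in the GENCODE M21 annotation of GRCm38. Value times gene span, from start to end with introns, fell on whole multiples of a single step per library, with a phase coherence of 0.739 to 0.796 (1 means exactly whole). Value times exon length gave at most 0.135. The step gives the depth, 32.7 to 48.7 M reads per library. In genes with a span under 5 kb and up to 20 reads, 83.1% to 86.3% of the recovered read numbers were whole within 0.1. The values do not show whether reads or fragments were counted. Because spans hold introns, a gene with long introns has a low RPKM for its read number. The deposited log2 fold change is, in all 18174 rows, the log2 ratio of the authors' group means with 0.001 added to each. The deposited q value is the Benjamini-Hochberg adjustment of the deposited p-value in all 18174 rows, and the test behind it is not given in the sources used here. Of the 18174 rows, 92 had no span in M21 and were left out of the tests. A gene symbol that repeats was kept for the row with that name in M21, and the 49 further rows were labelled by gene ID. Per-library columns that match no sample number 0.

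The fixed design assumed read counts, for which a count model was to be the main test. The values are RPKM, so edgeR and DESeq2 were not run, though recovered read numbers were tested with voom as an alternative. In their place limma 3.58.1 in R 4.3.3 was fitted to log2 of scaled RPM plus 0.5 (lmFit, eBayes with trend and robust options), with group as the only term. RPM, reads per M reads, is the RPKM times the span in kilobases. RPM was divided by an unweighted trimmed mean of M values per library (30% of ratios and 5% of averages trimmed at each end). Genes were tested when at least 3 libraries had the equivalent of 10 reads in the median library and all libraries together had 15, which left 15235 genes. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A log2 fold change on this scale understates the change of genes near 0.5 RPM. Means ± SD are of scaled RPKM, the deposited value divided by the library's scaling factor. This form of the test was settled after first results had been seen on deposited RPKM plus 0.01 without composition scaling. The low-read filter is that of the design. The design was written for read counts, so the unweighted scaling and the 0.5 RPM added before the log should not be read as fixed beforehand. The RPKM form is among the alternatives.

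The 43 gene lists, 23 of processes and 20 of cell types, and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Of the 43 lists 27 passed with the preset correlation, 14 higher and 13 lower in cold. With an estimated correlation 0 passed, and 0 had an unadjusted p under 0.05. With fry 30 passed, which include all 27. Named genes are Th, Cirbp, Rbm3 and a further gene fixed with them, the 12 largest rises and 12 largest falls, and examples from each list. The rises and falls were taken among genes past the threshold with separated groups, a mean log2 RPM of at least 1 and a proper gene symbol. List examples are up to 4 members past the threshold by smallest p, of which the text gives a part, and some named genes are not reported here. Several lists share members, and some markers are expressed by more than a single cell type.

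Replicates were compared before averaging. Within groups the chi-square per degree of freedom of recovered reads was 15.4 to 85.1, so no libraries agreed within sampling noise. The labels number the replicates 1 to 3 in both groups without stating a shared litter or day. Deviations from the group means correlated between same-numbered libraries at 0.114, 0.149 and 0.155 across genes, each above 0.1, so the numbers were treated as possible pairs. The fit with the replicate number as a block is among the alternatives.

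The procedure was tested on simulated data: counts for the real genes were drawn from the real mean levels and library sizes with a dispersion of 0.0106, 67, 67 and 66 genes were changed by 1.5-fold, 2-fold and 4-fold, and values were converted to rounded RPKM. For the simulated comparison of cold with room temperature over 15248 genes, 64.2% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 7 of 15048 unchanged genes were called. A changed list was found, and 0 of the unchanged lists were called. Genes were drawn independently of each other, whereas the endothelial list has an estimated correlation of 0.91 in the data. The simulation therefore did not try the list tests on correlated genes. It also changed few genes, in both directions alike, so it did not try the scaling under a broad change.

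Alternatives planned before the data were examined were the replicate block, median-of-ratios, upper-quartile and deposited (library total) scaling, voom on recovered reads, no low-read filter, a mean of at least 1 RPM, leaving out mitochondrial and haemoglobin genes, leaving out each library, a log2 fold change of at least 1, and the other list tests. The plan was written for read counts, so voom on recovered reads and the deposited scaling should not be read as fixed beforehand in these forms. Added after seeing the data were pseudocounts of 0.1 and 2 RPM, deposited RPKM plus 0.01 in genes with a mean of at least 0.05, and a cell make-up score as covariate. The score is the mean log2 value of alveolar and endothelial markers minus that of club and ciliated markers in each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.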

Results

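Lung RNA was sequenced from male mice of the inbred laboratory strain C57BL/6J that were kept at room temperature or held at 4 °C for 6 h. Each of the 2 groups had 3 libraries, which the labels call biological replicates without saying whether each came from its own animal. The p-values below therefore measure the spread between these libraries. The deposited values are RPKM per gene span, that is reads per kilobase from the start to the end of the gene, introns included, and per M reads, where M stands for mega. The depth recovered from the steps between low values was 39.8 to 48.7 M reads or fragments in the room temperature libraries and 32.7 to 35.1 M in the cold libraries, and 55.0% to 55.6% of these lay in listed genes. Over the 15235 genes tested, Pearson's r of log2 values between libraries, which is a correlation across genes, was 0.961 to 0.986 within the room temperature group. It was 0.989 to 0.991 within the cold group and 0.784 to 0.890 between groups. The first principal component held 90.2% of the variance and separated the groups, and the second held 4.71%. Room temperature replicate 3 lay at −44.0 on the first component, between the other room temperature libraries (−81.3 and −94.2) and the cold libraries (69.4 to 77.9).

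The comparison of cold with room temperature asks which lung transcripts respond to acute cold, within a study of nerve fibres that contain tyrosine hydroxylase and of their contact with lung epithelium. Transcripts of the conducting airway were lower in the cold libraries, and those of alveolar epithelium, endothelium and several blood cell types were higher. Stress hormone targets and immediate early genes were also higher, and genes of mitochondrial respiration, ribosomes, fatty acid oxidation, cholesterol biosynthesis and protein folding were lower. These list calls rest on a preset correlation between genes, and 0 of 43 lists passed with an estimated correlation (smallest adjusted p = 0.58). Scgb1a1, the main secretory protein of club cells, alone took 9.48% ± 0.548 (SD, n = 3) of the reads in listed genes at room temperature and 3.06% ± 0.359 (SD, n = 3) in cold. It is named for its share of the reads, which was seen before it was chosen. With limma and Benjamini-Hochberg adjustment over all genes tested, 5442 genes were higher and 5298 lower in cold, so 50.7% of the called genes were higher. Of these, 2628 and 2453 changed by at least 1 on the log2 scale. With 10740 of the 15235 genes tested called, calls in both directions were also common outside the lists. Under the deposited scaling, which uses library totals only, 7033 genes were higher and 3766 lower (65.1% higher), and the median of all genes moved from 0.01 to 0.29 on the log2 scale. Changes below are relative to the composition-scaled median unless the deposited scaling is named. With the cell make-up score of each library as a covariate, an alternative chosen after seeing the data, 16 genes were called higher and 61 lower. That score, alveolar and endothelial minus airway marker means, is nearly collinear with the group. All 3 libraries of one group lay beyond the 3 of the other for 76.2% of the genes, against 10% by chance. The authors' deposited table has 2317 genes higher and 2175 lower at a q value under 0.05. Of those, 2105 and 1903 were also called here in the same direction, and none (0) was called in the opposite one.

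Airway epithelial transcripts fell as a group. All 16 ciliated cell markers tested were lower, with a median log2 change of −2.44, and so were all 15 club and secretory cell markers, with a median of −3.28. Dnah5, an outer arm dynein of motile cilia, fell from 0.957 ± 0.14 to 0.155 ± 0.0103 scaled RPKM (mean ± SD, n = 3 per group here and below), and Dnah9, another axonemal dynein, fell from 0.375 ± 0.0669 to 0.0618 ± 0.0031. Cyp2f2, a cytochrome P450 of club cells, fell from 645 ± 57.4 to 121 ± 16.4, and Cbr2, a carbonyl reductase of these cells, from 4023 ± 545 to 1015 ± 43.9. Of 15 neuroendocrine cell markers 12 were lower and 1 higher (median −1.13). Of 14 listed markers of tracheal cartilage and upper airway 5 were tested and 4 were lower. Sox9, a chondrocyte and progenitor factor, stood at 1.29 ± 0.168 against 0.13 ± 0.0377. The others called lower were the keratins Krt5 and Krt4 and Ltf, which airway glands and epithelium make. The counts of these 4 lists were the same adjusted over the list alone. All 4 lists passed camera (adjusted p = 5.1e-07 for ciliated, 8.4e-06 for club and secretory, 0.0056 for neuroendocrine and 0.020 for upper airway cells). Each had an adjusted p = 0.58 with an estimated correlation.

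Alveolar and endothelial transcripts were higher in the same libraries. Of 20 endothelial markers 19 rose and 0 fell, with a median log2 change of 3.98. Lyve1, a hyaluronan receptor of lymphatic and some other endothelium, rose from 1.54 ± 1.09 to 26.2 ± 2.8 scaled RPKM, and Vwf, the von Willebrand factor, from 0.233 ± 0.0775 to 1.10 ± 0.11. Of 13 alveolar type 1 cell markers 11 rose and 1 fell (median 2.63), with Hopx at 6.69 ± 0.911 against 17.1 ± 1.43 and Clic5 at 0.58 ± 0.217 against 3.46 ± 0.368. Of 14 alveolar type 2 cell markers 10 rose and 1 fell (median 2.54). Etv5, a transcription factor of these cells, rose from 0.172 ± 0.0719 to 0.889 ± 0.131, and the chemokine Cxcl15 from 10.6 ± 3.68 to 44.7 ± 11.5. The mucin gene Muc1, which airway cells also express, was the member that fell, from 72.8 ± 14.7 to 20.8 ± 2.81. Adjusted over the list alone, 11 type 1 markers rose and 2 fell, and the other counts were the same. The 3 lists passed camera (adjusted p = 5.3e-05 for endothelium, 0.0093 for type 1 and 0.025 for type 2 cells) and had an adjusted p = 0.58 with an estimated correlation. The type 2 list had an adjusted p of 0.059 without cold replicate 2 and of 0.064 under the deposited scaling, both by camera.

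**Figure D1:**
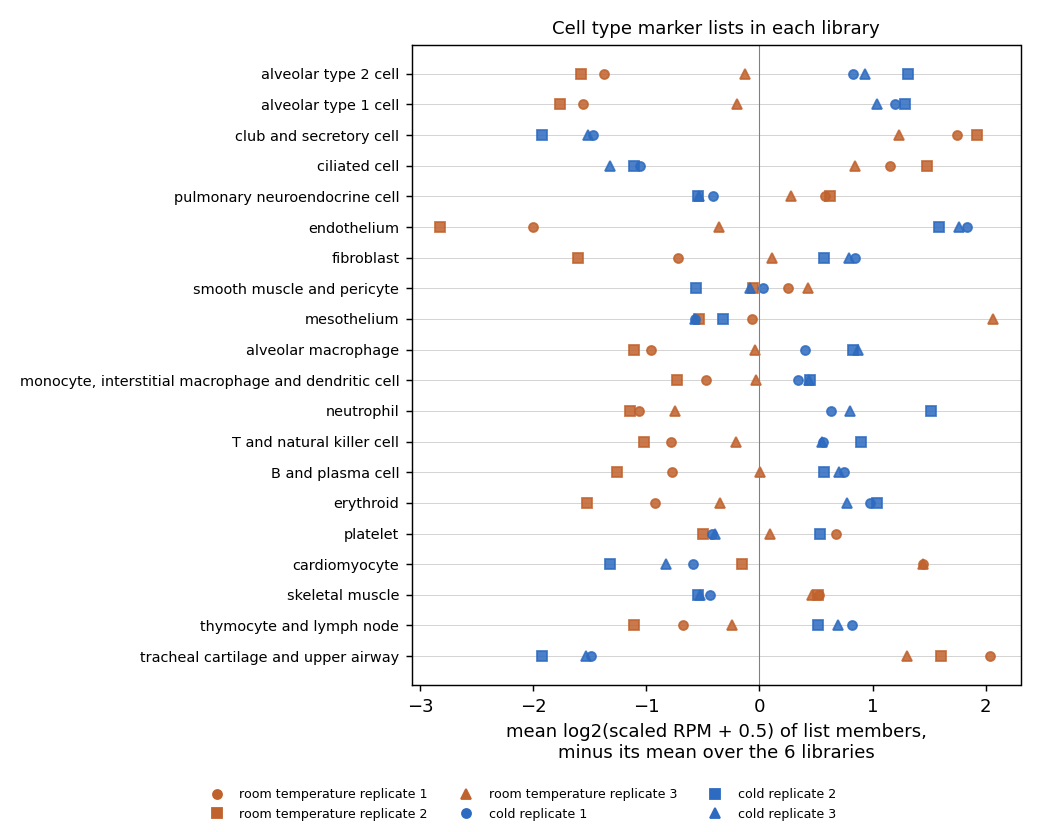
Mean log2 value of each cell type marker list in each library (x axis: mean of log2 of scaled RPM plus 0.5 over the list's members, minus its mean over the 6 libraries; y axis: lists; each point is a library). The 3 cold libraries lie above all room temperature libraries for endothelium and alveolar cells and below them for ciliated and club cells, and room temperature replicate 3 is the nearest to cold in these lists.

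Fibroblast and alveolar macrophage markers did not pass as lists. Of 16 fibroblast markers 11 rose and 4 fell (median 2.10; camera adjusted p = 0.069), or 11 and 1 under the deposited scaling (median 2.36), and Pdgfra, a receptor of alveolar fibroblasts, rose from 0.338 ± 0.212 to 4.30 ± 0.922 scaled RPKM. Of 14 alveolar macrophage markers 11 rose and 3 fell (median 1.84; adjusted p = 0.094). Smooth muscle and pericyte markers split into 6 higher and 8 lower of 16 (median −0.89, and −0.57 under the deposited scaling; adjusted p = 0.36), and the contractile genes Des and Cnn1 fell from 78.2 ± 8.93 to 9.48 ± 2.81 and from 26.8 ± 4.18 to 3.87 ± 1.1. Of 10 mesothelial markers 0 rose and 3 fell (median −1.11; adjusted p = 0.23). In the mesothelial list room temperature replicate 3 lay 2.06 above the mean of the 6 libraries, and the other 5 lay between 0.07 and 0.571 below it. The counts adjusted over the list alone were the same. Without room temperature replicate 3 the fibroblast list had an adjusted p of 0.0077 and the macrophage list of 0.023. The macrophage list also passed without cold replicate 1 (adjusted p = 0.036) and with the replicate number as a block (0.048). With all 6 libraries and no block, the fibroblast list had an adjusted p = 0.74 and the macrophage list an adjusted p = 0.58 with an estimated correlation.

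Markers of neutrophils, lymphocytes, monocytes and erythroid cells were higher in cold as lists, and those of platelets were not called. Of 15 neutrophil markers 13 rose and 2 fell, with a median log2 change of 2.30. S100a8 and S100a9, the calprotectin subunits of neutrophils, rose from 1.10 ± 0.321 to 31.8 ± 13.9 and from 0.39 ± 0.154 to 11.2 ± 5.83 scaled RPKM. Ltf, lactoferrin, which airway glands and epithelium also make, fell from 29.8 ± 13.2 to 0.636 ± 0.206. Of 16 T and natural killer cell markers 15 rose and 0 fell (median 1.31), with the co-receptor Cd8a at 0.0631 ± 0.0544 against 0.374 ± 0.0628. Of 12 B and plasma cell markers 9 rose and 0 fell (median 1.39), with Ms4a1, which encodes CD20, at 0.0216 ± 0.0198 against 0.159 ± 0.0367. Of 14 listed thymocyte and lymph node markers 8 were tested, of which 7 rose and 0 fell (median 1.51). Those with the smallest p were Fcer2a, Cd1d1, Lef1 and Cr2, and Cr2 is also in the B cell list. Of 20 markers of monocytes, interstitial macrophages and dendritic cells 9 rose and 0 fell (median 0.59). Of 11 erythroid markers 9 rose and 1 fell (median 2.41), with the adult beta globin gene Hbb-bs at 27.8 ± 20.8 against 245 ± 14.4. Of 12 platelet markers 1 rose and 1 fell (median −0.18, and 0.11 under the deposited scaling; camera adjusted p = 0.67). Adjusted over the list alone, 7 monocyte markers rose, 0 platelet markers rose and 1 fell, and the other counts were the same. The 6 lists other than platelets passed camera, with adjusted p of 0.0040 for neutrophils, 0.0015 for T and natural killer cells and 0.024 for B cells. Camera's adjusted p was 0.019 for the thymocyte and lymph node list, 0.024 for monocytes and 0.017 for erythroid cells. Each had an adjusted p = 0.58 with an estimated correlation. Under the deposited scaling the monocyte, B cell and thymocyte lists had adjusted p of 0.053, 0.067 and 0.050, without room temperature replicate 2 the monocyte list had 0.068, and without mitochondrial and haemoglobin genes the erythroid list had 0.096. The endothelial list moved with these lists, including in room temperature replicate 3.

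Cardiomyocyte and adipocyte genes were lower in cold. Of 19 cardiomyocyte markers 0 rose and 15 fell (median −1.87; camera adjusted p = 0.0031, and adjusted p = 0.58 with an estimated correlation). Room temperature replicate 2 lay at −0.15 relative to the list's mean over the libraries, nearer to the cold libraries than to replicates 1 and 3 (1.45 each). Myl7, the atrial myosin light chain, fell from 71.4 ± 36.1 to 10.7 ± 3.75 scaled RPKM and the muscle creatine kinase Ckm from 1.80 ± 0.771 to 0.265 ± 0.105. Of 10 skeletal muscle markers 2 rose and 5 fell (median −0.53; adjusted p = 0.27), and 3 rose and 3 fell under the deposited scaling (median −0.30). Of 16 adipocyte and thermogenic genes 3 rose and 11 fell (median −1.46; adjusted p = 0.042, and adjusted p = 0.58 with an estimated correlation). Gpd1, a glycerol phosphate dehydrogenase, fell from 8.86 ± 1.24 to 2.17 ± 0.364, the lipid droplet gene Cidea from 0.215 ± 0.058 to 0.0233 ± 0.0062 and the adipokine gene Adipoq from 1.00 ± 0.524 to 0.125 ± 0.0635. The counts adjusted over the list alone were the same. The adipocyte list had adjusted p between 0.050 and 0.093 under 5 alternatives, the highest without cold replicate 2. The airway markers were lower in the same libraries.

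Among genes whose groups did not overlap, those with the largest rise included several that endothelial cells express, and those with the largest fall several of airway epithelium. Of the 12 largest rises, Tmem100, Cd93, Calcrl, Ccm2l and Adgrl4, known from endothelium, and Edn1, which encodes the vasoconstrictor endothelin 1, rose by 4.84 to 5.56 on the log2 scale. Edn1 went from 0.293 ± 0.236 to 14.5 ± 5.61 scaled RPKM (log2 change 5.42 ± 0.52 SE, adjusted p = 0.00020). Slc6a2, the noradrenaline transporter, went from 0.0733 ± 0.0911 to 2.38 ± 0.758 (log2 change 5.30 ± 0.70 SE, adjusted p = 0.00073). The other genes were the ceramidase Acer2, the kinesin gene Stard9, the matrix phosphoprotein gene Spp1, Cyp1a1, a target of the aryl hydrocarbon receptor, and the myeloid gene Slfn4. Slfn4 and Cyp1a1 had the largest SD relative to the mean among the cold libraries for these 12 genes, at 2.61 ± 2.98 and 12.6 ± 8.99. The 12 genes with the largest fall were led by Acta1, skeletal muscle alpha actin, at 20.4 ± 4.39 against 0.0907 ± 0.026 (log2 change −6.30 ± 0.18 SE, adjusted p = 1.8e-05). Next came the basal cell keratins Krt5 (10.8 ± 5.0 against 0.101 ± 0.084) and Krt15 (31.4 ± 16.7 against 0.476 ± 0.237). Of the antimicrobial and mucosal secretory genes, Bpifa1 fell from 1010.4 ± 425 to 29.8 ± 16.7, Reg3g from 291 ± 99.9 to 10.4 ± 6.03 and Bpifb1 from 67.0 ± 24.4 to 1.38 ± 0.754, and Ltf, Clca1, Tff2 and Fcgbp fell by 4.68 to 5.43 on the log2 scale. The lipoxygenase gene Alox15 and Basp1 completed the set. Each of these 24 genes was separated between groups, and the marker lists of airway and endothelium moved with them.

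**Figure D2:**
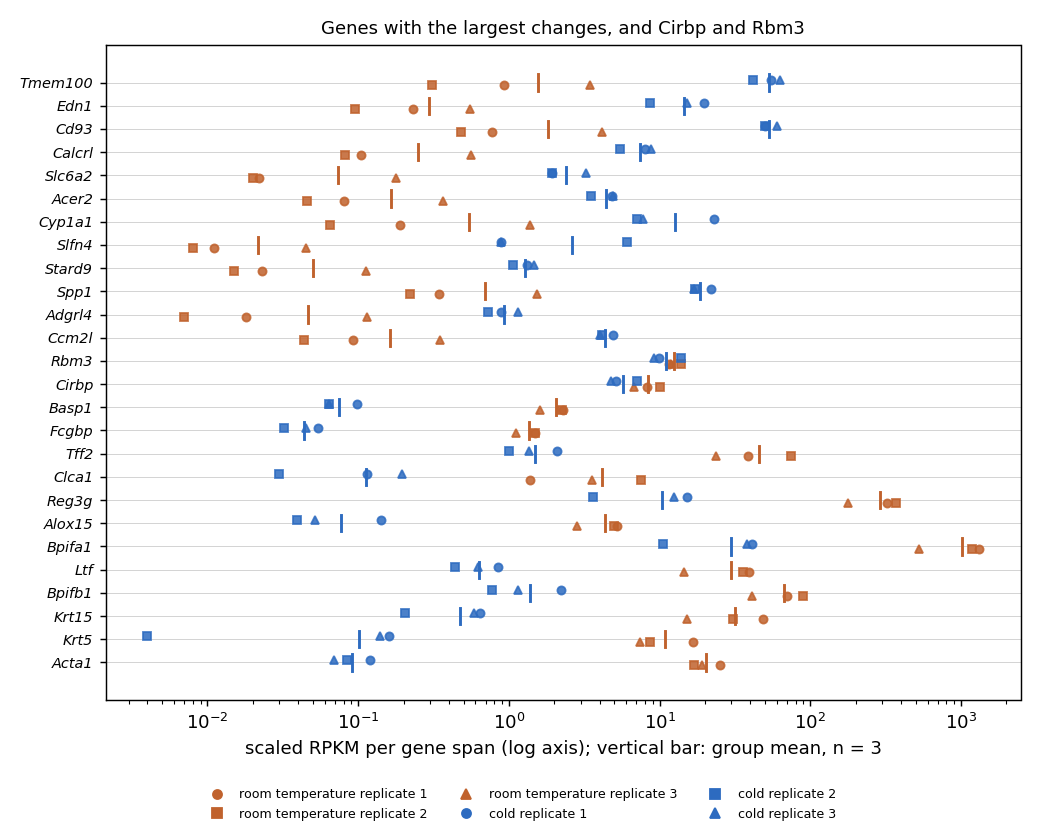
Scaled RPKM per gene span of the 12 genes with the largest rise and the 12 with the largest fall, with Cirbp and Rbm3 (x axis: scaled RPKM on a log axis; y axis: genes by log2 change; points are libraries and vertical bars group means, n = 3). The groups are apart for all genes but Cirbp and Rbm3, and room temperature replicate 3 is the highest room temperature library for each of the 12 genes that rose.

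Genes listed for sympathetic nerve fibres changed in both directions, and Th had too few reads to test. Th, the gene of tyrosine hydroxylase (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128 in GENCODE M21 on GRCm38), was listed at 0.001, 0.002 and 0 RPKM in the room temperature libraries and at 0 in the 3 cold libraries. The values above 0 correspond to about 1.53 and 3.74 reads before allowing for their rounding, so a difference was not detectable at this depth. Of 12 tested nerve genes 4 rose and 4 fell (median −0.35). Besides Slc6a2, the growth-associated Stmn2 rose from 0.062 ± 0.0336 to 0.451 ± 0.0191 scaled RPKM and the vesicular monoamine transporter Slc18a2 from 0.0476 ± 0.0113 to 0.117 ± 0.0199. The neurotrophin receptor Ngfr fell from 0.307 ± 0.121 to 0.0206 ± 0.0124. Camera gave an adjusted p of 0.84, and the list's mean was of the opposite sign to its median. Of 21 adrenergic receptor and signalling genes 11 rose and 5 fell (median 0.60; camera adjusted p = 0.19). The arrestin gene Arrb1 rose from 0.608 ± 0.0799 to 1.99 ± 0.301. The alpha 2A receptor gene Adra2a fell from 4.24 ± 2.28 to 0.248 ± 0.061 and Prkar2b, a regulatory subunit of protein kinase A, from 0.649 ± 0.108 to 0.138 ± 0.0064. Both counts were the same adjusted over the list alone. Over all 15235 genes tested 5442 were higher and 5298 lower, so calls in both directions are not particular to these lists. With the deposited scaling 4 nerve genes rose and 3 fell (median −0.19), and 13 adrenergic genes rose and 4 fell (median 0.90). The endothelial markers rose and the airway markers fell in the same libraries. In room temperature replicates 1, 2 and 3 Slc6a2 stood at 0.022, 0.02 and 0.178 scaled RPKM and Ngfr at 0.41, 0.337 and 0.173. Replicate 3 was thus nearest to cold, as in the endothelial and airway lists. Which cells the transcripts of the nerve list came from was not tested.

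Secreted factors that have been linked to adipose thermogenesis split, with 10 of 23 higher and 6 lower (median 0.51; camera adjusted p = 0.47), and the same counts adjusted over the list alone. Vegfa, a vascular growth factor that is also in the alveolar type 1 list, rose from 2.78 ± 1.35 to 37.7 ± 2.39 scaled RPKM. Fst, which encodes the activin antagonist follistatin, rose 8.32-fold from 0.18 ± 0.0926. Fndc5, the irisin precursor, fell from 2.66 ± 0.389 to 0.456 ± 0.11, and the activin subunit Inhbb from 5.99 ± 0.591 to 1.67 ± 0.172. Over all 15235 genes tested 10740 were called. Endothelial and alveolar markers rose and airway markers fell in these libraries.

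Targets of glucocorticoids, immediate early genes and targets of cAMP signalling were higher in cold. Of 19 glucocorticoid response genes 14 rose and 2 fell (median 1.40). Map3k6 rose from 0.718 ± 0.0733 to 5.41 ± 0.408 scaled RPKM, the transcription factors Klf9 and Zbtb16 from 2.46 ± 0.359 to 7.96 ± 0.315 and from 0.0385 ± 0.015 to 0.246 ± 0.0312, and the kinase gene Sgk1 from 0.29 ± 0.0683 to 0.978 ± 0.142. Of 23 immediate early genes 15 rose and 2 fell (median 1.19), with the phosphatase gene Dusp1 at 10.7 ± 3.46 against 73.6 ± 19.0 and Klf4 at 11.7 ± 2.42 against 31.2 ± 2.6. The 6 not called include Fos and Egr1, named here outside the rule, whose groups overlapped (limma adjusted p = 0.10 and 0.19). Of 16 cAMP and CREB response genes 10 rose and 1 fell (median 0.96). The phosphodiesterase gene Pde4b rose from 0.011 ± 0.0052 to 0.238 ± 0.0467 and Crem, a cAMP responsive modulator, from 0.0828 ± 0.0116 to 0.178 ± 0.0146. Ppargc1a, a coactivator of mitochondrial genes, was the member that fell, from 0.103 ± 0.0157 to 0.0394 ± 0.0034. Adjusted over the list alone, 15 glucocorticoid genes rose and 2 fell, and the other counts were the same. The lists passed camera with adjusted p of 0.0013, 0.0065 and 0.012, and each had an adjusted p = 0.58 with an estimated correlation. Endothelial and alveolar markers rose in the same libraries.

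Clock genes changed in both directions. Of 13 genes of the Per and Rev-erb arm 6 rose and 5 fell (median −0.03; camera adjusted p = 0.81, with the mean and the test of the opposite sign). Ciart and Per2, both repressors of the clock, rose from 0.973 ± 0.245 to 6.93 ± 1.08 and from 0.81 ± 0.116 to 2.01 ± 0.21 scaled RPKM. The clock output factor Dbp fell from 19.0 ± 4.62 to 5.27 ± 1.36 and the deubiquitinase gene Usp2 from 2.12 ± 0.332 to 0.612 ± 0.111. Of 6 genes of the Bmal1 arm 2 rose and 2 fell (median −0.18; adjusted p = 0.80). Clock rose from 0.216 ± 0.0148 to 0.465 ± 0.0512 and Arntl, which encodes BMAL1, from 0.0163 ± 0.0023 to 0.0313 ± 0.0088. Npas2 fell from 0.031 ± 0.005 to 0.0066 ± 0.0022. Counts adjusted over the list alone were the same. Calls in both directions are not particular to clock genes, as 5442 of all 15235 genes tested were higher and 5298 lower. Under the deposited scaling both medians were above 0, at 0.29 and 0.12. Airway markers fell and endothelial and alveolar markers rose in the same libraries.

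The genes of both RNA-binding proteins known to be induced by mild cold in cultured cells were not among those called higher. Cirbp (ENSMUSG00000045193, chromosome 10, 80165985 to 80172786) fell from 8.38 ± 1.65 to 5.68 ± 1.27 scaled RPKM with overlapping groups (log2 change −0.56 ± 0.19 SE, adjusted p = 0.032 by limma). It had an adjusted p of 0.24 under the deposited scaling and of 0.079 to 0.11 without room temperature replicate 1 or 2 or cold replicate 1 or 3. Rbm3 (ENSMUSG00000031167, chromosome X, 8138975 to 8145880) stood at 12.4 ± 1.23 and 10.9 ± 2.47 (log2 change −0.20 ± 0.16 SE, adjusted p = 0.30), and at −0.37 with an adjusted p of 0.037 without cold replicate 2. Of the 8 temperature-sensitive RNA-binding and splicing genes 6 rose and 1, Cirbp, fell (median 0.87; camera adjusted p = 0.034, and adjusted p = 0.58 with an estimated correlation). The splicing kinases Clk1 and Clk4 rose from 2.69 ± 0.939 to 16.1 ± 1.06 and from 0.883 ± 0.2 to 3.58 ± 0.139, and the splicing factor gene Srsf5 from 25.9 ± 1.39 to 67.2 ± 1.12. This list had adjusted p of 0.068 with the replicate number as a block, 0.070 without cold replicate 2 and 0.058 under the deposited scaling. Of 20 heat shock genes 2 rose and 11 fell (median −0.89), with the chaperone gene Hsp90ab1 at 293 ± 43.2 against 93.2 ± 16.5 and its partner Fkbp4 at 25.6 ± 1.79 against 11.3 ± 0.836. Of 20 endoplasmic reticulum stress genes 3 rose and 12 fell (median −0.58), with the folding factors Sdf2l1 at 10.2 ± 1.51 against 1.97 ± 0.63 and Pdia4 at 6.15 ± 0.506 against 2.69 ± 0.22. Of the latter, 4 rose and 12 fell adjusted over the list alone, and the heat shock and splicing counts were the same. Both lists passed camera (adjusted p = 0.024 and 0.029) and had an adjusted p = 0.58 with an estimated correlation. Without room temperature replicate 3 the heat shock list had 0.056, and without replicate 2 the endoplasmic reticulum list had 0.066. In the heat shock list 3 genes rose and 11 fell under the deposited scaling (median −0.58), and in the endoplasmic reticulum list 4 rose and 9 fell (median −0.26). The airway markers fell in the same libraries.

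Genes of respiration, translation, fatty acid oxidation and cholesterol biosynthesis were lower in cold. All 22 nuclear genes of oxidative phosphorylation fell (median −0.90), as did 12 of 13 mitochondrially encoded genes (median −1.26) and 21 of 23 cytosolic ribosomal protein genes (median −0.62), and 0 members of these lists rose. The ATP synthase gene Atp5b fell from 74.1 ± 4.63 to 24.0 ± 1.7 scaled RPKM, Cox4i1 from 30.2 ± 2.19 to 11.6 ± 0.931 and mt-Co2 from 126 ± 26.8 to 45.0 ± 3.96, both subunits of cytochrome oxidase, and the ribosomal Rps2 and Rpl8 from 138 ± 10.1 to 53.5 ± 4.15 and from 186 ± 14.3 to 84.1 ± 4.16. Under the deposited scaling 21, 12 and 15 members fell and 0 rose, with medians of −0.59, −0.94 and −0.30. Of 24 PPAR targets and fatty acid oxidation genes 2 rose and 15 fell (median −0.65). The lipid droplet gene Plin5 went from 3.49 ± 0.882 to 0.508 ± 0.115 and the thioesterase gene Acot1 from 7.24 ± 1.65 to 1.51 ± 0.133. Of 19 cholesterol biosynthesis genes 1 rose and 11 fell (median −0.58), with the squalene epoxidase Sqle at 4.98 ± 1.13 against 1.26 ± 0.0951. Under the deposited scaling 4 PPAR and fatty acid oxidation genes rose and 10 fell (median −0.34), and 3 cholesterol genes rose and 8 fell (median −0.26). In the ribosomal list 22 genes fell adjusted over the list alone, and the other counts were the same. The 5 lists passed camera, with adjusted p of 5.1e-07, 0.0013, 1.0e-05, 0.012 and 0.020 in the order given, and each had an adjusted p = 0.58 with an estimated correlation. Lipogenesis genes (8 of 20 higher and 5 lower, median 0.18; adjusted p = 0.64) and genes of hypoxia and glycolysis (5 of 19 higher and 10 lower, median −0.41; 0.23) did not pass as lists, and under the deposited scaling 10 and 4 of the former (median 0.50) and 9 and 9 of the latter (median −0.10) were called. The ciliated and club cell markers fell in the same libraries.

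Inflammatory genes were higher, with 15 of 20 NF-kB cytokine and adhesion genes up and 2 down (median 0.92; camera adjusted p = 0.0093, and adjusted p = 0.58 with an estimated correlation). Il1b, the interleukin 1 beta gene, rose from 0.0701 ± 0.0217 to 2.18 ± 1.2 scaled RPKM and the adhesion molecule gene Icam1 from 2.14 ± 1.09 to 12.4 ± 1.64. Neutrophil and endothelial markers rose in the same libraries. Of 22 interferon response genes 3 rose and 4 fell (median −0.28; adjusted p = 0.79), or 5 and 2 under the deposited scaling (median 0.04), of 24 cell cycle genes 7 rose and 5 fell (median 0.15; 0.81), and of 21 extracellular matrix genes 11 rose and 4 fell (median 0.62; 0.25). With the deposited scaling 10 cell cycle genes rose and 3 fell (median 0.39), and 12 matrix genes rose and 3 fell (median 0.93). The collagen crosslinking enzyme gene Lox rose from 0.591 ± 0.209 to 10.2 ± 3.05, and Col1a1, a chain of type I collagen, fell from 8.48 ± 1.1 to 3.77 ± 0.566. Adjusted over the list alone, 2 interferon genes rose and 0 fell, 6 cell cycle genes rose and 5 fell, and the other counts were the same.

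**Figure D3:**
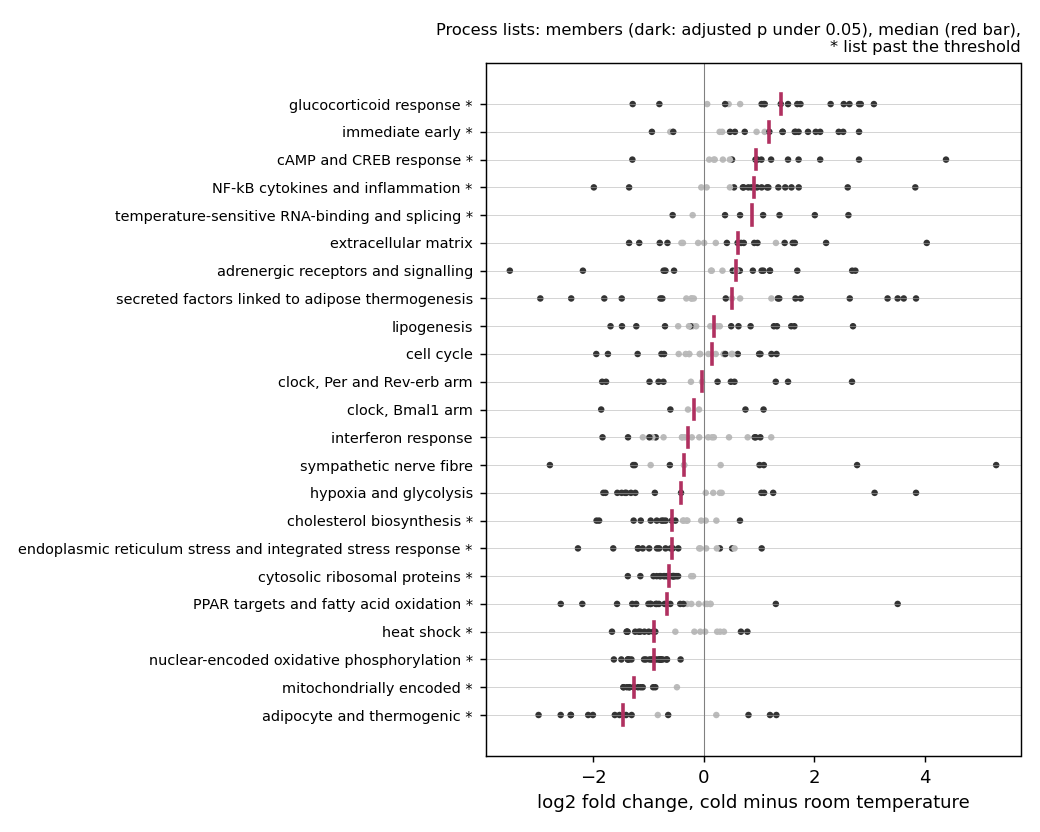
Log2 fold change, cold minus room temperature, of the members of each process list (x axis: log2 fold change from limma; y axis: lists by median; dark points have an adjusted p under 0.05, red bars are medians, and a star marks lists past the camera threshold). Glucocorticoid, immediate early and cAMP lists lie to the right, with medians of 1.40, 1.19 and 0.96, and the respiratory and ribosomal lists to the left.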

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

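The pseudocounts, the RPKM form and the cell make-up covariate were chosen after seeing the data, and the other alternatives before the data were examined. The counts of genes higher in cold and genes lower in cold (5442 and 5298) stayed within 1.5 times in all settings but the covariate and the fold threshold. They lay at 4761 to 5667 and 4658 to 5405 when each library was left out in turn, with 24 to 28 gene lists past the threshold. At an absolute log2 fold change of at least 1 they were 2628 and 2453. With the replicate block 5379 genes were higher, 5277 lower and 27 gene lists past the threshold. It changed the call of the temperature-sensitive RNA-binding list (adjusted p = 0.068) and of the alveolar macrophage list (0.048) and no other call among the 96 named genes for which alternatives were run and the 43 lists. With an estimated correlation 0 gene lists passed, against 27 with the preset 0.01 and 30 with fry, which added the adrenergic, hypoxia and skeletal muscle lists (adjusted p = 0.041, 0.00094 and 0.00064). Deposited RPKM plus 0.01 lost the erythroid (adjusted p = 0.061) and B cell (0.15) lists, and left the thymocyte list with too few members to test (24 lists passed). Upper-quartile scaling, no filter, a mean of at least 1 read per M reads, and voom lost the adipocyte list (0.050, 0.055, 0.054 and 0.062), and the mean of at least 1 also left the upper airway list with too few members to test (25 lists passed). Without mitochondrial and haemoglobin genes the erythroid list was lost (0.096) and the mitochondrially encoded list had no genes (25 lists passed). Median-of-ratios scaling and both other pseudocounts changed no call among the 96 named genes and 43 lists. The DESeq2 and edgeR alternatives of the design were not run, since the deposited values are not counts. Recovered read numbers were tested with voom only. Depth limits genes such as Th, with about 3.74 reads, before allowing for rounding, in its highest library.

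With the cell make-up score as a covariate, genes higher in cold numbered 16 and genes lower in cold 61, and 18 gene lists passed. The score is built from 5 of the lists and nearly collinear with the group (−4.34, −5.06 and −2.48 at room temperature, 1.41, 1.72 and 1.53 in cold), and the cause of each change was not tested. Of 96 named genes 5 kept their direction and side of the threshold, 77 lost their call and 14 turned in direction, none of these 14 past the threshold. Of the 77, 5 had a log2 change as large or larger than without the covariate (Srsf5 1.51, Fndc5 −2.72, Ckm −4.43, Myl7 −4.66 and Col1a1 −1.77), 15 a smaller change within 1.5 times and 57 a change smaller by more. Their median SE went from 0.214 to 0.543, so a lost call does not by itself show that the change was removed. The SE with the covariate was 0.931 to 4.23 times that without it, and in some genes the estimate shrank at a like SE. Ccm2l went from 4.84 to 0.009 (SE 0.556 and 0.517) and Lyve1 from 4.28 to 0.189 (SE 0.474 and 0.475). The log2 changes of the 14 were Cirbp 0.43, Tmem100 −0.76, Cd93 −0.87, Calcrl −0.40, Slc6a2 −0.48, Acer2 −0.67, Cyp1a1 −2.60, Stard9 −0.44, Spp1 −0.12, Adgrl4 −2.11, Icam1 −0.0575, Cd8a −0.32, Ms4a1 −0.075 and Hbb-bs −1.20. The lists that turned had camera adjusted p of 0.39 (cholesterol biosynthesis), 0.000806 (interferon response), 0.0014 (extracellular matrix), 0.000806 (alveolar type 2), 0.067 (alveolar type 1), 4.4e-06 (endothelium), 5.1e-05 (fibroblast), 0.0078 (alveolar macrophage), 0.013 (monocyte, interstitial macrophage and dendritic cell), 0.20 (T and natural killer cell), 0.0099 (B and plasma cell), 0.39 (erythroid) and 0.78 (thymocyte and lymph node). The lists that lost their call had 0.18 (immediate early), 0.067 (cAMP and CREB), 0.067 (temperature-sensitive RNA-binding), 0.83 (endoplasmic reticulum stress), 0.10 (PPAR and fatty acid oxidation), 0.18 (mitochondrially encoded), 0.17 (NF-kB), 0.47 (adipocyte), 0.063 (ribosomal) and 0.78 (neuroendocrine), and those that gained it 8.5e-15 (mesothelium) and 0.0099 (smooth muscle and pericyte). Call and direction were kept by the glucocorticoid, heat shock, nuclear oxidative phosphorylation, neutrophil, cardiomyocyte and upper airway lists. The club and ciliated lists, which are part of the score, kept them too. The alveolar type 1, alveolar type 2 and endothelium lists, which turned, are also part of the score. In the mesothelium list, room temperature replicate 3 stood at 2.06 relative to the mean over the libraries, and the others at −0.571 to −0.07. That library also had the room temperature score nearest to cold, so the mesothelium call rests largely on 1 library.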

Other observations

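Shares of reads also differed between the groups. Mitochondrially encoded genes took 3.40% ± 0.683 (SD, n = 3) of the reads in listed genes at room temperature and 1.74% ± 0.17 (SD, n = 3) in cold, and haemoglobin genes 0.0226% ± 0.0184 and 0.181% ± 0.022. The 10 most abundant genes of each library took 19.0% ± 1.65 and 8.78% ± 1.04. The cardiomyocyte list stood at 1.45, −0.15 and 1.45 relative to its mean over the libraries in room temperature replicates 1, 2 and 3, and at −0.59, −1.33 and −0.83 in the cold ones. No permutation test of these shares could go below p = 0.10 with 3 against 3 libraries.

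The make-up and abundant-gene tests of the airway pattern and the count of splits were chosen only after the result was seen, and the other tests before. The first pattern is lower airway lists with higher alveolar and endothelial lists. A few abundant genes taking reads from all others would move both alike, but the endothelial and ciliated medians differed by 6.42 (SE 0.32) on the log2 scale. A trend with gene span would be removed by random lists matched on span and expression, against which the difference was still 6.41 (SD 0.43). The share of intron reads of each gene was not matched, so unequal counting of introns is not excluded. Different shares of airway and distal lung cells remain as a hypothesis, since room temperature libraries differed along the same genes: replicate 3 minus 2 had r = 0.609 with mean cold minus replicate 1 across 15235 genes (Spearman's rho 0.606), and genes are not independent replicates. The spread of make-up scores among room temperature libraries (−4.34, −5.06 and −2.48) is not an effect of the cold. Whether the difference between groups comes from the piece of lung taken or from the cold itself was not tested. Any difference between groups in the piece taken would follow the cold.

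The second pattern is the rise of the glucocorticoid, immediate early and cAMP lists, 53 genes with a median log2 change of 1.05. Gene span is argued against, as this median lay at percentile 100 of random lists matched on span and expression. The share of intron reads was not matched here either, so unequal counting of introns is not excluded. After removal of the make-up axis, each gene's difference of room temperature replicate 3 from the mean of replicates 1 and 2 scaled to the change in make-up score, the residual median of 0.35 also lay at percentile 100. That percentile was set beforehand to exclude make-up, but as a bound it was wrong, a judgement made after its value was seen, because the same step left the marker lists themselves outside their random ranges, with club cells at −1.84 and endothelium at −1.83. Make-up and a response to cold therefore cannot be told apart for these genes.

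The third pattern is the fall of the oxidative phosphorylation, mitochondrially encoded and ribosomal protein lists, 58 genes with a median of −0.82. Gene span is argued against as the whole cause, since the median lay at percentile 0.53 of matched random lists, but those lists were low too, with a median of −0.56. Intron read shares were again not matched, so unequal counting of introns is not excluded. After the make-up axis was removed the residual median was −0.38, at percentile 1.63. By list it was −0.71 for nuclear oxidative phosphorylation, below its random range (from −0.41), and −0.31 and −0.30 for mitochondrially encoded and ribosomal protein genes, within theirs (from −0.58 and −0.55). The failure of that step on the marker lists leaves make-up and cold unseparated here as well.

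Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many called genes (10740), and the highest of the others gave 0. The 10 splits are too few for a share under 0.05. In every other split both parts hold libraries of both groups, so the difference between groups widens the spread. Their 0 calls are therefore no separate support. Of the other splits, 3 also part all 3 pairs of same-numbered libraries and called 0 genes, and 6 part 1 pair.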
